A study of Homo sapiens with 8 samples.

How the data were processed

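Gene expression was measured by RNA sequencing of poly(A)-selected RNA in 8 libraries from LUHMES cells, a conditionally immortalised human mesencephalic line that becomes dopaminergic neurons once differentiated. Per the labels' protocols, cells were differentiated for 6 days in a defined medium with dbcAMP at 1 mM, GDNF at 2 ng/mL and tetracycline at 1 µg/mL. They then received antimycin A at 25 µM and oligomycin at 10 µM, or the DMSO vehicle, for 8 h. RNA was isolated on a silica column (RNeasy), and 1.3 µg of it entered library preparation with the KAPA mRNA HyperPrep kit. The titles give differentiation numbers 2 to 5 in both groups. The series text sets 4 independent treated batches against 4 independent vehicle batches, with 4 technical replicates in each, and does not say whether a number is a batch shared by the groups. The deposited tables hold 1 library per number and group, so n is 4 per group throughout.

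The authors deposited a gene table and a transcript table for each library, which hold estimated counts, effective lengths and TPM, per the file headers. These columns have the layout that salmon writes, and the quantifier and its settings are not given in the sources used here. The TPM values are, per the file headers, scaled by effective length and to a fixed sum per library by the authors' quantifier. HISAT2, SAMtools, StringTie and the hg38 build are named, without versions or roles, per the submitters' processing notes. The authors' deposited table of coding genes holds a normalised signal per library whose unit is not named, a log2 fold change of treated over vehicle cells, a p-value and a false discovery rate. The authors' deposited table of lncRNAs holds FPKM values per library, per the file headers. Its fold change column is headed as log2, and the 1018 intact lines hold a linear ratio of vehicle over treated. The other 159 of its 1177 lines hold values of another kind under the same headings, such as group means in place of single libraries, and were left out. An annotation of 269 lncRNAs that the authors list as unknown came from a transcript assembly, and 225 of them have intact FPKM values. Whether the counting used strand is not given in the sources used here.

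The gene tables list 62826 genes, of which 125 come from the assembly and carry no Ensembl identifier. Gene types and coordinates came from GENCODE release 29 on the hg38 build, and symbols from the gene name table supplied with it. A gene type was found for 58262 genes there and for another 356 by symbol. The transcript tables list 253512 transcripts, 202856 of them from genes in that annotation.

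Estimated counts were rounded to whole numbers. Genes were filtered with filterByExpr and scaled with TMM factors. Treated cells were compared with vehicle cells by the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with no covariate and a Benjamini-Hochberg adjusted p under 0.05 as the threshold. All fold changes below are log2 of treated over vehicle, some with a standard error (SE). For edgeR this SE is the size of the fold change over the square root of its F statistic, so it restates the test. Levels are CPM, read counts scaled to a common library total, on TMM-scaled library sizes, or FPKM where stated, as mean ± SD (n = 4 per group). Gene lists, 39 in number and written before the data were examined, were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Each list test was adjusted over the lists, and camera with an estimated correlation and fry stood beside it. Assembled lncRNAs were tested on log2(FPKM + 1) with limma, since the assembly identifiers of the lncRNA table and those of the count tables come from different runs and could not be matched as planned. A fold change on that scale understates the change of low genes. Transcript usage was tested with diffSpliceDGE of edgeR and Simes p-values per gene, on transcripts with at least 10 reads in at least 4 libraries. Uncertainty in dividing reads among transcripts is not part of that test. Shares of reads were compared by an exact two-sided permutation test over the 70 assignments of 8 libraries, whose smallest p is 0.0286.

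Genes named in the text follow a rule fixed before the data were examined. It takes 27 genes reported whatever their result. To these it adds the 10 largest rises and the 10 largest falls among genes past the threshold with a mean CPM of at least 5, a symbol and the same sign in all 4 same-numbered pairs. It also takes, at a mean CPM of at least 1, the 5 largest rises and falls among lncRNA genes, and at a mean FPKM of at least 1 the 3 largest each way among unannotated lncRNAs. That FPKM limit replaced the planned CPM limit once the assembly identifiers could not be matched. From each list come up to 2 rising and 2 falling members with the smallest adjusted p, and from transcript usage the 5 genes with the smallest adjusted p. Genes named outside this rule are given as such, and some genes that it takes are not reported here.

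The tests of genes, gene lists, transcript usage and FPKM values were run on simulated data. With changes planted in 200 genes of the treated against vehicle comparison, edgeR recovered 65.7% of genes at 1.5-fold, 92.5% at 2-fold and 100% at 4-fold, with 12 false calls among 19785 genes. Far fewer genes changed there than in the data, so scaling under a broad change was not tested. Changes were planted only in genes above a minimum of expected reads, with each gene's spread set by the trend over abundance. No library was made to stand apart. Recovery in low genes and false calls from gene-specific spread or an outlying library were therefore not tested. The list test called the 1 shifted list of 20 genes at 1.5-fold and none of 100 unshifted lists. The simulated genes varied independently, so this gives no rate of false calls for lists whose genes move together. Usage changes that moved 30% of the reads of a gene's largest transcript to its next largest were recovered in 38.5% of 200 genes, with 4 false calls among 11691. These 200 genes were also drawn above a minimum of reads. A shift of 1 in log2(FPKM + 1) was recovered in 60% of 200 simulated lncRNAs, with 7 false calls among 1018. Levels and spreads in that simulation were set values rather than taken from the data, so these rates may not hold for the data.

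Alternatives fixed before the data were examined were other scaling factors, library totals without a composition factor, 2 other filters on low counts, DESeq2 1.42.0, limma-voom, an effective length offset, leaving out mtDNA genes, a log2 threshold of 1, the differentiation number as a block, and each library left out in turn. The FPKM settings added after seeing the data were a pseudocount of 0.1, a mean FPKM of at least 1 and scaling to equal medians. Tables and exact tests were made with Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and NumPy 2.4.6, and plots with Matplotlib 3.10.9.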

Results

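LUHMES neurons were exposed for 8 h to antimycin A, an inhibitor of respiratory complex III, together with oligomycin, an inhibitor of the ATP synthase, or to vehicle. The comparison asks which transcripts change when mitochondrial respiration and ATP synthesis are blocked at the same time. The 4 treated libraries held 101, 93.8, 109 and 98.3 M estimated reads and the 4 vehicle libraries 93.7, 103, 98.6 and 110 M, in the order of differentiation numbers 2 to 5. No pair of libraries in a group agreed within sampling noise (chi-square per degree of freedom 14 to 435). Batches are independent by the series text, so p-values of single genes and of shares of reads measure the spread between differentiations. Camera with a preset correlation compares listed genes with other genes, and some permutation tests below run over genes. Their p-values do not measure that spread. The first principal component of log2 CPM held 71.5% of the variance and separated the groups. The second held 10.3%, with vehicle replicate 2 at -54.8 and the other vehicle libraries at 14.5 to 22.9.

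Treated neurons strongly raised genes of amino acid supply and stress signalling. SLC7A11, the cystine importer, rose from 1.27 ± 0.405 to 655 ± 48.9 CPM (log2 fold change 9.01 ± 0.223 SE). STC2, a secreted glycoprotein of the integrated stress response, rose from 0.806 ± 0.152 to 189 ± 6.45 CPM (7.88 ± 0.125), and CHAC1, a glutathione-degrading enzyme, from 2.08 ± 0.487 to 153 ± 29.4 CPM (6.20 ± 0.209). The other largest rises among the more abundant genes were HSPA6 (8.42), a stress-inducible HSP70, the transcription factor genes JDP2 (7.65), CEBPB (6.70) and MEF2B (6.27), the hedgehog-binding HHIP (6.94), the netrin receptor UNC5B (6.76) and the peptide hormone gene ADM2 (6.03). Among genes with a symbol and a mean CPM of at least 5, the largest falls were those of KCNS2, a potassium channel subunit, from 18.6 ± 3.02 to 1.88 ± 0.251 CPM (-3.31 ± 0.141), and PRDM16-DT, a lncRNA, from 176 ± 28.2 to 18.6 ± 4.00 CPM (-3.25 ± 0.178).

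Falls of a similar size were seen for the apelin receptor gene APLNR (-2.98), the transcription factor ATOH8 (-2.91), the morphogen SHH (-2.49), the mtDNA gene MT-ND6 (-2.39), the keratin KRT40 (-2.38), the cyclin CCND1 (-2.23) and RBM12 (-2.21). MTND2P28, a nuclear copy of MT-ND2 that can share its reads, fell by 2.32 on the log2 scale, and by 0.96 without vehicle replicate 2. In hg38 coordinates, SLC7A11 (ENSG00000151012.13) lies on chromosome 4 from 138164097 to 138242349, STC2 (ENSG00000113739.11) on chromosome 5 from 173314713 to 173329503, CHAC1 (ENSG00000128965.13) on chromosome 15 from 40952962 to 40956519, KCNS2 (ENSG00000156486.8) on chromosome 8 from 98427022 to 98432848 and PRDM16-DT (ENSG00000177133.14) on chromosome 1 from 3059615 to 3068437. The adjusted p of these 5 genes ran from 1.2e-10 for STC2 to 3.3e-07 for PRDM16-DT (edgeR quasi-likelihood test), each with the same sign in all 4 same-numbered pairs.

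Of 19785 genes tested, 11461 changed, 5484 higher and 5977 lower in treated cells, and 3419 of them by a log2 fold change of at least 1 in size. Among 14636 protein-coding genes 8668 changed, 4395 higher and 4273 lower, or 8689 when adjusted within the class. When libraries were scaled by their totals alone, the coding split moved to 3359 higher and 5123 lower and that of all genes to 4280 and 7023.

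Every tested member of the integrated stress response list rose, 20 of 20, with a median log2 fold change of 3.62 (camera adjusted p = 8.5e-15, and adjusted p = 0.057 with an estimated correlation). ATF4, the transcription factor at the centre of this response, rose from 252 ± 31.4 to 821 ± 41.3 CPM (1.70 ± 0.0928). Its partners and targets DDIT3 (3.6), ATF3 (4.46), TRIB3 (5.37) and SESN2 (3.65) rose, and the mitochondrial stress cytokine gene GDF15 rose from 0.517 ± 0.108 to 21.8 ± 5.02 CPM (5.39). FGF21, a second such cytokine gene, stood at 0.365 ± 0.0647 CPM in treated cells, with no read in 3 of 4 vehicle libraries and 0.00864 CPM in vehicle replicate 5.

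Amino acid supply rose along with it. In the list of amino acid and one-carbon synthesis 13 of 14 genes rose and 1 fell (median 2.37, adjusted p = 3.0e-09, and adjusted p = 0.14 with an estimated correlation). Asparagine synthetase ASNS rose from 103 ± 8.76 to 892 ± 42.2 CPM (3.11 ± 0.0803), the serine synthesis enzyme PSAT1 from 57.2 ± 5.61 to 687 ± 33.6 CPM (3.59) and the cysteine-forming CTH by 3.15, while the proline pathway enzyme ALDH18A1 fell (-0.84). The median of this list in vehicle replicate 2 lay at -0.25 log2 units from the other vehicle libraries. All 11 amino acid transporters rose (median 2.96, adjusted p = 3.0e-09, and adjusted p = 0.075 with an estimated correlation), among them the arginine transporter SLC7A1 from 77.5 ± 4.86 to 604 ± 18.4 CPM (2.96). Of 20 cytosolic aminoacyl-tRNA synthetases 13 rose and none fell (median 1.12, adjusted p = 8.7e-06, and adjusted p = 0.038 with an estimated correlation). The first by adjusted p were YARS1 (2.02) and CARS1 (2.34).

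In the endoplasmic reticulum unfolded protein response 21 of 23 genes rose, 22 adjusted over the list alone (median 1.14, adjusted p = 3.2e-12, and adjusted p = 0.0070 with an estimated correlation). The chaperone gene HSPA5 rose from 315 ± 21 to 1430 ± 59.7 CPM (2.18 ± 0.0703), the transcription factor XBP1 from 40.1 ± 2.73 to 374 ± 5.46 CPM (3.22) and HERPUD1 by 3.03. Among NRF2 targets 13 of 18 rose and none fell (median 0.86, adjusted p = 4.2e-07, and adjusted p = 0.075 with an estimated correlation). Heme oxygenase HMOX1 rose from 12.9 ± 3.04 to 285 ± 51.6 CPM (4.47), and the glutathione synthesis gene GCLM by 2.73. SLC7A11 is a member of this list and of the transporter list. Of 16 cytosolic heat shock genes 11 rose and 2 fell (median 0.39, adjusted p = 0.0097, and adjusted p = 0.38 with an estimated correlation). CRYAB (3.53) and DNAJB1 (1.89) rose, while the constitutive HSPA8 (-0.33) and DNAJA1 (-0.26) fell.

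Of the 39 lists 38 had tested members, 16 passed the camera test and 2 of these also with an estimated correlation, the synthetases and the unfolded protein response. Counts adjusted over the list alone were the same as those over all genes tested for 28 lists, and for the other 10 they stand beside the count.

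**Figure D1:**
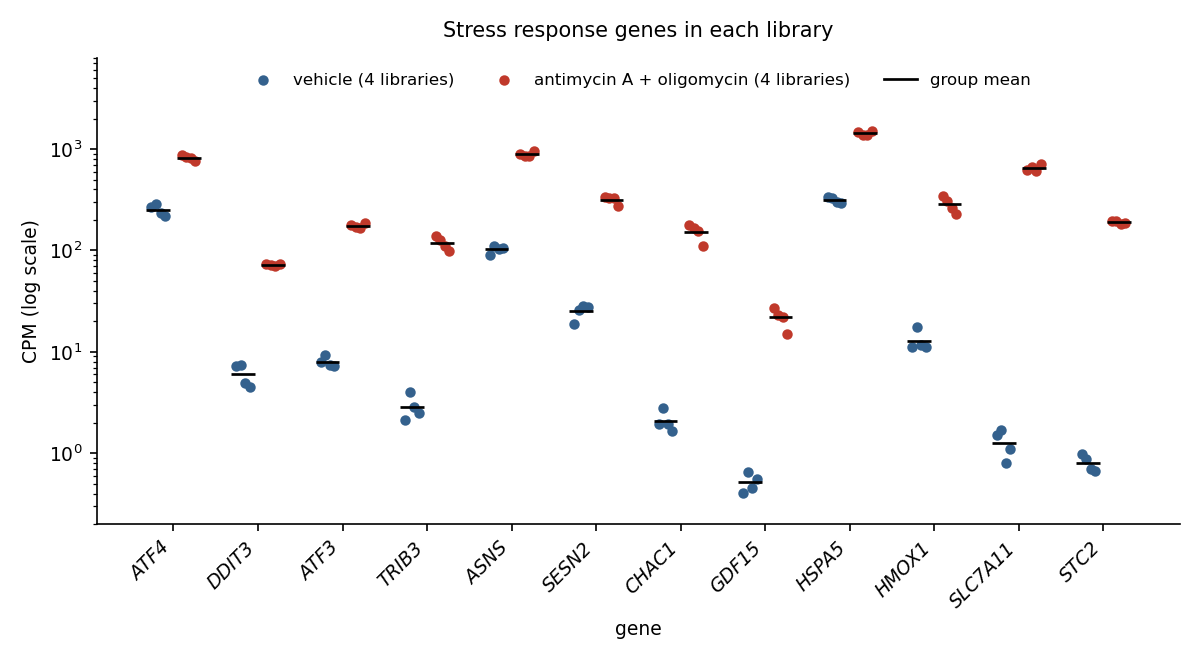
CPM (log axis) of 12 stress genes in each library of treated and vehicle cells, with points for libraries and bars at group means. ATF4 means were 821 and 252 CPM and SLC7A11 means 655 and 1.27 CPM, treated and vehicle.

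**Figure D2:**
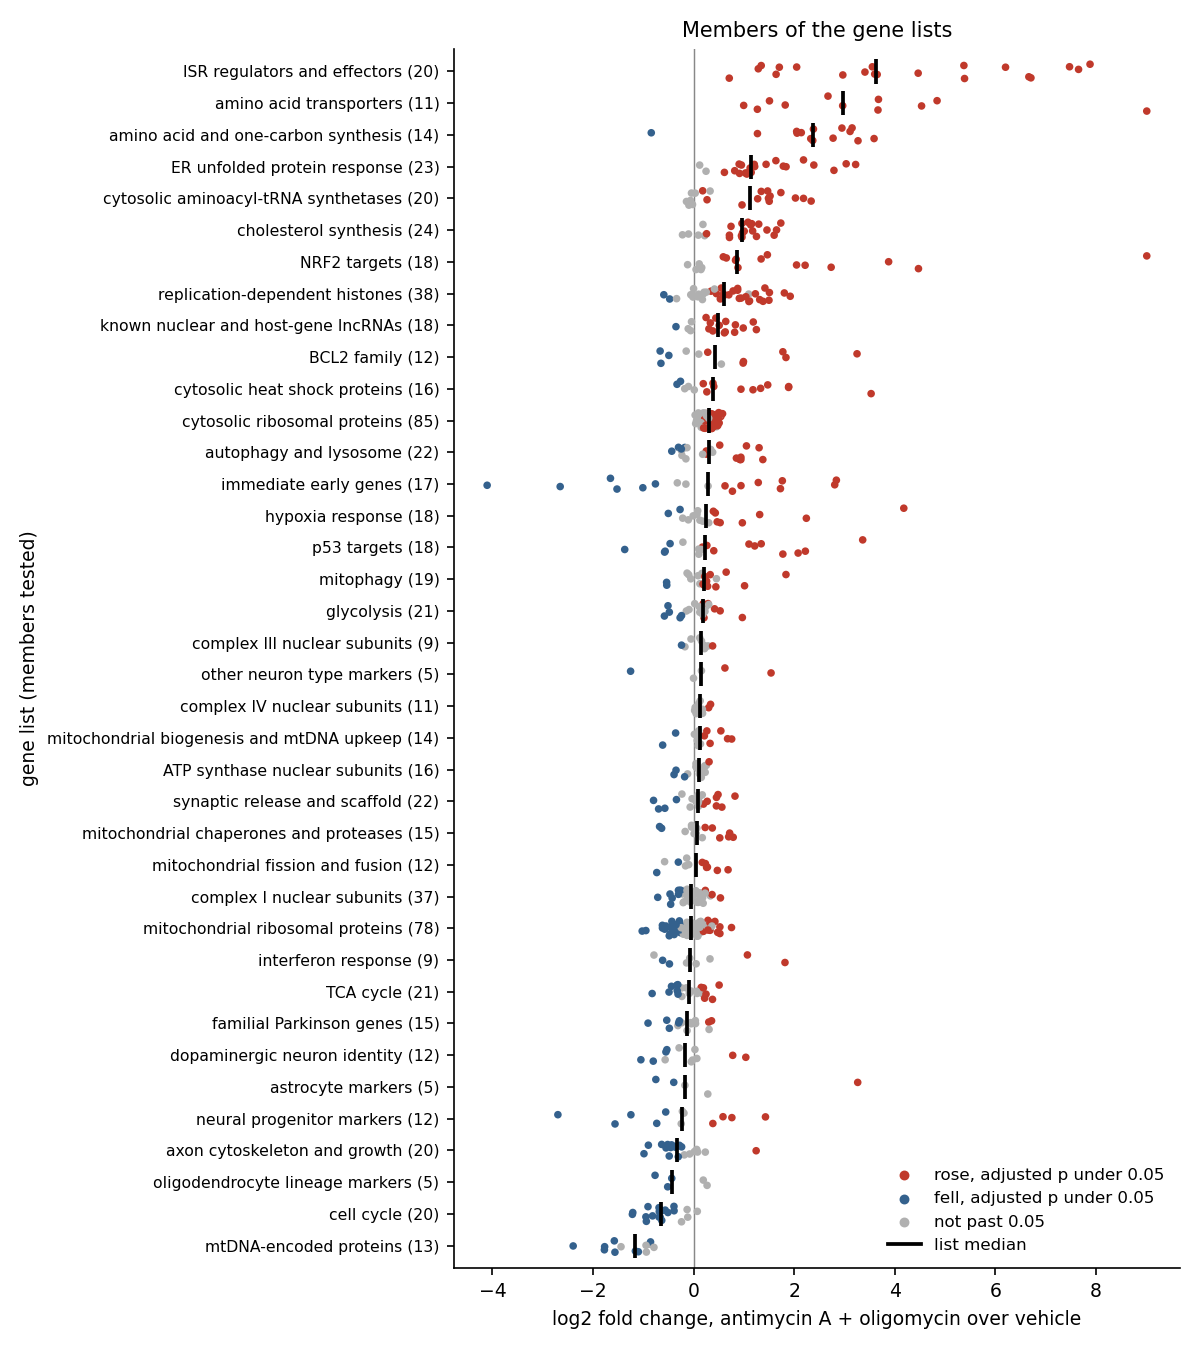
Log2 fold change (treated over vehicle) of each tested member of 38 gene lists, with the list median marked and points coloured by whether the gene passed the test. Medians run from 3.62 for the integrated stress response to -1.16 for mtDNA-encoded proteins.

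Transcripts of the mitochondrial genome moved in opposite directions by class. The 13 mtDNA-encoded mRNAs took 2.63 ± 0.343% of reads in treated cells and 5.82 ± 3.80% in vehicle cells (difference -3.19 points, exact permutation p = 0.0286, the smallest of 70 assignments), and each treated library lay below each vehicle library. Within same-numbered pairs the exact sign-flip p = 0.125, the smallest of 16 sign patterns, so a paired test cannot make this call. Vehicle replicate 2 held 11.5%, the other vehicle libraries 3.27 to 4.33%, and without it the vehicle mean was 3.93 ± 0.580% and the difference -1.30 points (exact p = 0.0286). Leaving out any 1 treated library left differences of -3.03 to -3.28 points with an exact p = 0.114. The mtDNA rRNAs took 3.29 ± 0.581% of reads in treated and 1.04 ± 0.575% in vehicle cells (exact p = 0.0286). Their ratio to the mRNAs was 1.25 ± 0.101 against 0.186 ± 0.0179 (exact p = 0.0286).

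The light-strand mRNA MT-ND6 fell from 90.2 ± 42.1 to 17.2 ± 2.37 CPM (-2.39 ± 0.272, and -2.02 without vehicle replicate 2), and the complex I gene MT-ND2 fell by 1.77 on the log2 scale (-1.06 without that library). MT-ND5 (-1.77), MT-ND3 (-1.58), MT-ND1 (-1.56), MT-CYB (-1.16), MT-CO2 (-1.10) and MT-CO1 (-0.86) also fell, which makes 8 of 13, or 11 adjusted over the list alone. Without vehicle replicate 2 these 6 stood at -0.99, -0.93, -0.84, -0.55, -0.53 and -0.38, each past the threshold and over 1.5 times smaller. MT-ATP8 stood at -1.44, MT-ATP6 at -0.95, MT-ND4L at -0.94, MT-ND4 at -0.86 and MT-CO3 at -0.79, none past the threshold. Without that library they stood at -0.21, -0.26, -0.05, -0.14 and -0.27, of which MT-ATP6 passed (adjusted p = 0.034). MT-RNR1, the small mitochondrial rRNA, rose from 907 ± 567 to 6864 ± 1283 CPM (2.92 ± 0.359) and MT-RNR2, the large one, by 1.53. Apart from MT-ND6 and MT-ND2, the mtDNA genes in this paragraph were chosen because they make up the list or its rRNA counterpart.

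The list of mtDNA-encoded proteins had a median of -1.16 (adjusted p = 0.034, and adjusted p = 0.83 with an estimated correlation). Its call was lost without treated replicate 5 (adjusted p = 0.084), with library totals only (0.055) and by fry (0.081), and over all alternatives its adjusted p ran from 0.0078 to 0.83. The median of these genes in vehicle replicate 2 lay 1.79 log2 units above the other vehicle libraries. Without that library 9 of 13 passed, with a median of -0.53.

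**Figure D3:**
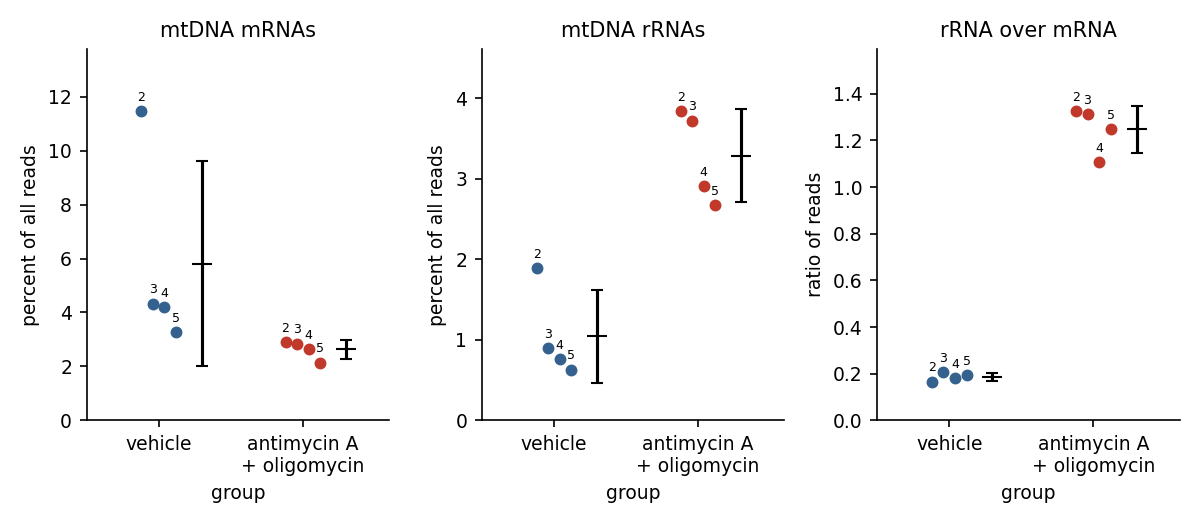
Percent of reads in mtDNA mRNAs, percent in mtDNA rRNAs, and their ratio in each library, numbered by differentiation, with mean ± SD per group. All treated libraries lie below all vehicle libraries in the first panel, where vehicle replicate 2 stands at 11.5%, and above them in the ratio, with means of 1.25 and 0.186.

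Nuclear genes of oxidative phosphorylation showed small changes both ways. Of 37 complex I subunit genes 3 rose and 7 fell (2 and 6 adjusted over the list alone, median -0.05, camera adjusted p = 0.61), with NDUFV2 (-0.71) and NDUFB3 (-0.46) lower and NDUFS4 (0.37) and NDUFB9 (0.23) higher. Of 9 complex III genes UQCRH rose (0.38) and UQCR10 fell (-0.24), with a list adjusted p of 0.58. Of 11 complex IV genes COX4I1 (0.30) and COX5A (0.34) rose, with a list adjusted p of 0.28. Of 16 ATP synthase genes 1 rose, ATP5MC2 (0.31), and 3 fell, with ATP5MC1 (-0.39) and ATP5MF (-0.18) the first by adjusted p (1 and 1 adjusted over the list alone, list adjusted p = 0.60). With library totals only, NDUFB9 (0.13), COX5A (0.24) and ATP5MC2 (0.21) did not pass, nor did ATP5MF without treated replicate 3 or vehicle replicate 4 or 5 (-0.16 to -0.17). Medians of the complex III and complex IV genes in vehicle replicate 2 lay at -0.34 and -0.27 log2 units from the other vehicle libraries, and those of complex I and the ATP synthase at -0.20 and -0.24.

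Mitochondrial ribosomal proteins were also divided. Of 78 genes 12 rose and 25 fell (11 and 24 adjusted over the list alone, median -0.06, camera adjusted p = 0.50). MRPS17 (-1.02) and MRPL24 (-0.95) fell, while MRPL48 (0.75) and MRPS5 (0.52) rose. Of 14 genes of biogenesis and mtDNA upkeep 6 rose and 2 fell (adjusted p = 0.28). The coactivator genes PPARGC1A (0.76) and PPARGC1B (0.54) rose, the former with no call under a length offset (0.52). TFB1M (-0.62, and -0.22 with no call under a length offset) and SSBP1 (-0.36) fell, and the mtDNA transcription factor TFAM stood at 0.10 ± 0.0883 (adjusted p = 0.36). Of 12 fission and fusion genes 6 rose and 2 fell (adjusted p = 0.69), among them MTFP1 (0.68) and MTFR1 (0.47) upward and DNM1L (-0.30) and MTFR2 (-0.73, and -0.52 with no call under a length offset) downward.

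Of 15 mitochondrial chaperone and protease genes 6 rose and 2 fell (median 0.06, camera adjusted p = 0.31). HSPA9, the matrix HSP70, rose from 308 ± 23.5 to 531 ± 17.5 CPM (0.79), TIMM17A by 0.72 and the protease gene LONP1 by 0.52, while OMA1 (-0.68) and HTRA2 (-0.64) fell. HSPD1 rose by 0.23 (adjusted p = 0.032), a call lost without treated replicate 4 or 5 or vehicle replicate 3 or 5 (0.18 to 0.24) and under 4 other settings. In the mitophagy list 10 of 19 rose and 2 fell (median 0.21, adjusted p = 0.072). The receptor genes SQSTM1, from 81.8 ± 9.12 to 292 ± 20.6 CPM (1.84), and CALCOCO2 (1.01) rose. FUNDC1, a receptor of the outer mitochondrial membrane, fell (-0.54). PINK1 stood at -0.13 ± 0.108 (adjusted p = 0.32), and passed at -0.23 without vehicle replicate 2. Among 22 autophagy and lysosome genes 11 rose and 4 fell (12 and 4 adjusted over the list alone, median 0.30, adjusted p = 0.034, and adjusted p = 0.38 with an estimated correlation), a list call lost without vehicle replicate 2 (adjusted p = 0.084), against coding genes alone (0.062) and with the differentiation number as a replicate block (0.058), in a range of 5.7e-05 to 0.38 over all alternatives. TFE3 (1.30) and GABARAPL1 (1.05) rose, and the cathepsin gene CTSB fell (-0.43).

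In cholesterol synthesis 19 of 24 genes rose and none fell, 20 adjusted over the list alone (median 0.97, camera adjusted p = 2.0e-07, and adjusted p = 0.40 with an estimated correlation). The sterol sensor partner INSIG1 rose from 71.2 ± 9.39 to 237 ± 14.8 CPM (1.73). The median of this list in vehicle replicate 2 was -0.32 log2 units from the other vehicle libraries. Of 21 glycolysis genes 6 rose and 5 fell (5 and 4 adjusted over the list alone, adjusted p = 0.43), with HK2 (0.97) and SLC2A3 (0.53) higher and the lactate transporter SLC16A1 (-0.51) and GPI (-0.27) lower. Its median in vehicle replicate 2 was -0.29 log2 units from the other vehicle libraries. Of 21 genes of the tricarboxylic acid cycle 6 rose and 7 fell (adjusted p = 0.58). OGDH, a subunit of the 2-oxoglutarate dehydrogenase, fell from 165 ± 7.66 to 93.2 ± 8.68 CPM (-0.82) and PDHB by 0.44 on the log2 scale, while SDHD (0.51) and IDH3A (0.37) rose. In the hypoxia list 8 of 18 rose and 2 fell (median 0.24, adjusted p = 0.025, and adjusted p = 0.38 with an estimated correlation), a call lost without vehicle replicate 2 (adjusted p = 0.080, in a range of 6.0e-05 to 0.38 over all alternatives). The angiogenic factor VEGFA rose from 36.3 ± 3.25 to 171 ± 15.7 CPM (2.24) and ANKRD37 by 1.31, while the glycolytic regulators PFKFB3 (-0.50) and PDK1 (-0.27, and -0.14 with no call under a length offset) fell. TXNIP, a thioredoxin inhibitor gene, fell from 54.8 ± 23.7 to 14.1 ± 0.946 CPM (-1.96 ± 0.270).

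Cytosolic ribosomal protein genes rose a little and together, 66 of 85 with none lower, and 71 adjusted over the list alone (median 0.31, camera adjusted p = 4.3e-08, and adjusted p = 0.38 with an estimated correlation). RPS15A rose by 0.44 and RPS3 from 465 ± 26.7 to 609 ± 15.9 CPM (0.39). Their median in vehicle replicate 2 was -0.19 log2 units from the other vehicle libraries.

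Genes of the axon and its growth fell. Of 20 such genes 13 fell and 1 rose (median -0.33, camera adjusted p = 0.031, and adjusted p = 0.44 with an estimated correlation). DPYSL2, a tubulin-binding protein of the growth cone, fell from 919 ± 37.2 to 464 ± 18.7 CPM (-0.99) and the tubulin gene TUBA1A from 4863 ± 205 to 3130 ± 60.3 CPM (-0.64), while STMN4 rose (1.24). Of 22 synaptic genes 7 rose and 4 fell (adjusted p = 0.54), with DLG4 (0.82) and CPLX1 (0.56) higher and HOMER1 (-0.57) lower.

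Markers of dopaminergic identity moved apart, with 2 of 12 tested genes higher and 4 lower (median -0.17, camera adjusted p = 0.60). TH, the rate-limiting enzyme of dopamine synthesis, rose from 7.48 ± 1.34 to 15.4 ± 3.10 CPM (1.04 ± 0.166, adjusted p = 3.9e-04) and the channel gene KCNJ6 by 0.78. DDC, which forms dopamine from its precursor, fell (-1.05) from a low level of 0.495 ± 0.101 CPM, and GCH1 fell (-0.55). The dopamine transporter gene SLC6A3 stood at 589 ± 69.4 CPM in vehicle and 570 ± 69.6 in treated cells (-0.05 ± 0.109, adjusted p = 0.73). Of 15 tested familial Parkinson genes 2 rose and 5 fell (adjusted p = 0.38), with DNAJC6 (-0.91) lower and FBXO7 (0.30) and PLA2G6 (0.36) higher, the latter with no call without treated replicate 2, 3 or 4 or vehicle replicate 2, 4 or 5 (0.28 to 0.37) or with a replicate block (0.35). Cell cycle genes fell, 16 of 20 with none higher (median -0.65, adjusted p = 1.2e-04, and adjusted p = 0.44 with an estimated correlation), among them RRM2 (-1.22) and BUB1 (-0.95).

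Long noncoding RNA genes fell more often than they rose. Of 2905 tested, 1702 changed (1707 adjusted within the class), 568 higher and 1134 lower in treated cells, and their share of reads was 1.49 ± 0.0445% against 1.63 ± 0.0207% (exact permutation p = 0.0286). After PRDM16-DT, the largest falls at a mean CPM of at least 1 were those of MAP3K9-DT (-2.54), ZNF778-DT (-2.31), LINC02870 (-2.24) and PDCD6IP-DT (-2.21), and 4 of these 5 are named as divergent transcripts of a neighbouring coding gene. The largest rises at that level were PDCD6-AHRR (3.28), a read-through gene whose reads overlap both coding genes and which did not pass in DESeq2, BAALC-AS2 (3.20, and 1.24 under a length offset), VLDLR-AS1 (3.0), LINC00654 (2.86) and MIR34AHG (2.19). VLDLR-AS1 overlaps VLDLR on the opposite strand, and VLDLR, named outside the rule for this overlap, rose by 2.97, so without stated strand use the reads of the pair cannot be told apart.

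Among 18 well-known nuclear and snoRNA host lncRNAs 14 rose and 1 fell (median 0.48, camera adjusted p = 8.5e-04, and adjusted p = 0.18 with an estimated correlation). The host gene SNHG1 rose from 59.7 ± 5.94 to 136 ± 3.04 CPM (1.19), ZFAS1 by 0.99 and GAS5 by 0.44, while MIAT fell (-0.35). NEAT1, the scaffold of paraspeckles, rose by 0.64, at 0.713 ± 0.0622 against 1.11 ± 0.112 CPM. MALAT1 rose by 0.38 (adjusted p = 0.046). That call was lost without any 1 library other than vehicle replicate 2 (0.31 to 0.41) and with a replicate block (0.41), and without that library the value was 0.58. In vehicle replicate 2 MALAT1 stood at 1510 CPM against 932 to 966 in the other vehicle libraries.

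Among the 225 unannotated lncRNAs of the authors' assembly 78 changed, 16 higher and 62 lower in treated cells (limma on log2(FPKM + 1)). With FPKM scaled to equal medians, chosen after seeing the data, 27 were higher and 44 lower. Before scaling, median FPKM was 1.15 in treated and 1.51 in vehicle cells. Without that scaling, 8 of 141 antisense overlapping unannotated lncRNAs rose and 34 fell, and 3 of 28 sense overlapping ones rose and 5 fell. Without stated strand use, their reads cannot be told apart from those of the overlapped genes. Of 48 intergenic ones 5 rose and 17 fell. Of 793 lncRNAs known to the authors' catalogue 68 rose and 310 fell, and with scaling to equal medians 125 were higher and 213 lower. The limit on overlapping reads also holds for the 347 antisense and 103 sense overlapping lncRNAs among them. Lnc-CRHR2, on chromosome 7 from 30621390 to 30622463 and antisense to the glycyl-tRNA synthetase gene GARS1, rose from 32.4 ± 8.90 to 152 ± 13.4 FPKM (2.24 ± 0.230). GARS1, also named outside the rule, rose by 2.18, and without stated strand use their reads cannot be told apart. Lnc-NMRK2 (1.56), on chromosome 19 from 3956898 to 3962151, overlaps DAPK3, and lnc-LIPI (1.93), on chromosome 21 from 8196269 to 8446210, spans genes of the 5.8S rRNA (limma adjusted p = 0.018, and a false discovery rate of 0.155 in the authors' deposited table).

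The lncRNA lnc-TTC34, on chromosome 1 from 2917137 to 2925447 with no annotated gene there, fell from 10.7 ± 2.15 to 0.628 ± 0.0920 FPKM (-2.82 ± 0.145). Lnc-PSMG4, on chromosome 6 from 3224630 to 3225725 and overlapping TUBB2B, fell from 53.5 ± 9.27 to 8.47 ± 2.77 FPKM (-2.56). Its reads cannot be told apart from those of TUBB2B without stated strand use. Lnc-MT-ND6, which spans mtDNA positions 5761 to 14673, fell from 321 ± 267 to 61.0 ± 64.0 FPKM (-2.39, limma adjusted p = 0.049), while the authors' deposited table gives it a false discovery rate of 0.344. Treated replicate 2 stood at 157 FPKM against 22.8 to 38.2 in the other treated libraries, and vehicle replicates 2 to 5 at 696, 252, 275 and 62.3. Its call was lost without treated replicate 3, 4 or 5 or vehicle replicate 2, 3 or 4 (-1.87 to -2.36, limma adjusted p from 0.097 to 0.11) and under all 3 added FPKM settings. It was kept without treated replicate 2 (-3.0) or vehicle replicate 5 (-3.02) and with a replicate block. By the false discovery rate in the authors' deposited table, 243 of the intact lncRNAs passed 0.05, and 206 of these were lower in treated cells.

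Transcript shares changed in 1005 of 11691 genes with at least a pair of tested transcripts, and in 426 of them by 10 points or more. When the libraries were regrouped with equal numbers of treated and vehicle libraries on each side, the same test called 57 to 108 genes. Part of the 1005 may therefore not come from the treatment. In CSNK1D, the casein kinase 1 delta gene, transcript CSNK1D-202 rose from 42.6 ± 4.34 to 80.1 ± 1.29% of the gene's reads while CSNK1D-203 fell from 34.0 ± 2.75 to 1.25 ± 0.512% (gene adjusted p = 1.3e-26, edgeR). In SC5D, a sterol desaturase gene, SC5D-201 rose from 28.0 ± 3.57 to 62.7 ± 0.942% and SC5D-202 fell from 59.0 ± 4.36 to 33.9 ± 1.14%. RBFOX3-213, of the neuronal splicing factor gene, went from 0 reads, which allows up to 0.0376%, to 22.1 ± 12.5%. DHX30-202 went from 8.82 ± 1.47% to 0 reads, which allows up to 0.00798%. In the pseudogene HERC2P3, whose reads are uncertain, HERC2P3-205 went from 0, which allows up to 0.0506%, to 49.0 ± 7.58%.

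XBP1, whose shares were looked at after its values were seen, held 3.81 ± 2.14% of its reads in XBP1-202 in vehicle and 28.8 ± 0.826% in treated cells, while XBP1-201 fell from 89.8 ± 2.63 to 63.8 ± 1.01% (edgeR adjusted p = 6.7e-09). XBP1-202 lacks 26 bases that lie within XBP1-201, but it is also shorter elsewhere (1131 against 1850 bases), so its share does not measure the loss of these 26 bases alone. The enzyme IRE1, encoded by ERN1, is known to cut a short intron from XBP1 mRNA. The upper limits for transcripts without reads use 3 counts over the group and cover counting error only. The usage count fell to 580, 583, 578 and 636 genes without treated replicate 2, 3, 4 and 5, each over 1.5 times fewer.

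**Figure D4:**
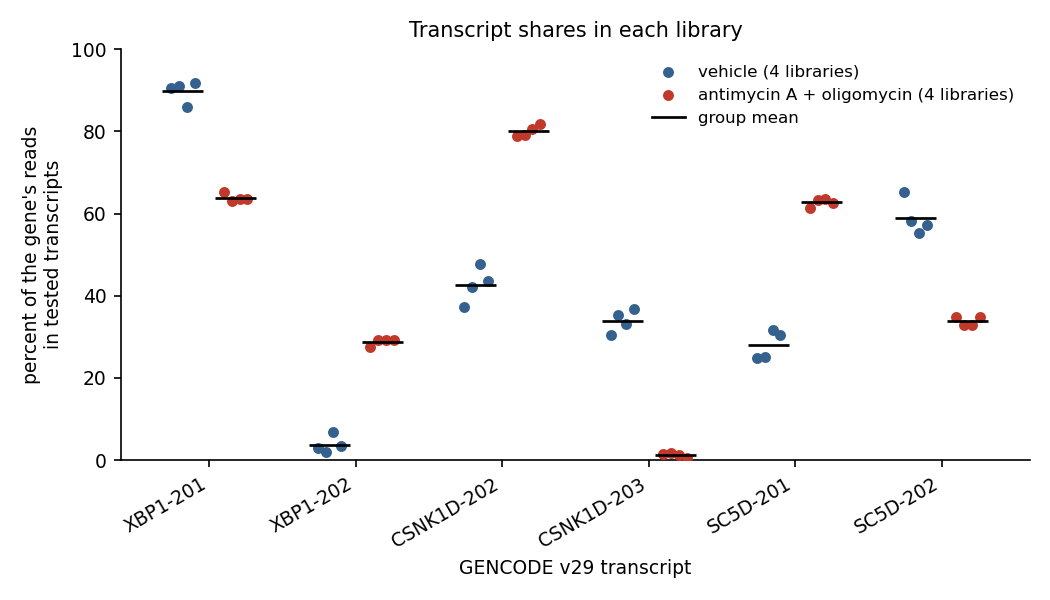
Percent of each gene's reads in transcripts of XBP1, CSNK1D and SC5D in each library, with bars at group means. XBP1-202 means were 28.8% in treated and 3.81% in vehicle cells, and CSNK1D-203 means 1.25% and 34.0%.

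For coding genes the fold changes were set beside those of the authors' deposited table, made from the same samples and so no independent evidence. Among 12096 matched genes 98.0% had the same sign, with a Pearson correlation across genes of 0.988, where genes are not independent replicates. The authors' deposited table had 6995 of these genes past a false discovery rate of 0.05 and the test here 7334, with 6758 past in both and 6757 of those in the same direction.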

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

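The tests of a difference shared with treated replicate 2, of nuclear copies of mtDNA genes, of vehicle replicate 2 alone, of scaling and of lncRNAs beside coding promoters were chosen only after the result was seen. Those of gene length, GC content and overlap were written before their own results but after related values were known. In 362 groups of 4 libraries the gap of the most distant library to its nearest neighbour was divided by the group's range, and 27 groups lay past the critical ratio, where chance gives about 18. Of these, 12 were in vehicle replicate 2, 7 in vehicle replicate 3, 3 in treated replicate 5, 2 each in vehicle replicates 4 and 5, and 1 in treated replicate 2.

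Vehicle replicate 2 stood apart in its share of mtDNA mRNA reads (ratio 0.870, 11.5% against 3.27 to 4.33%), in the share of its 10 most abundant genes (0.900, 12.5% against 6.23 to 6.86%), in transcripts of the nonsense-mediated decay class (0.901, 2.74% against 2.08 to 2.15%) and on the second principal component (0.892). It was also far from the other vehicle libraries for MTND2P28 (0.964), PFKFB3 (0.949), MALAT1 (0.941), MT-ND2 (0.924), HOMER1 (0.897), TIMM17A (0.893), DNM1L (0.835) and LONP1 (0.830). Over 14345 genes, 214 differed more than 2-fold from the mean of the other vehicle libraries, 86 higher and 128 lower.

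Against a mixed culture, 27 markers of astrocytes, oligodendrocytes, other neurons and progenitors had a median log2 difference of -0.0512 in this library, with 0 markers above 1. Against mtDNA reads alone, its median deviation without mtDNA genes was 0.214, 3.09 times the largest of the other vehicle libraries (0.0695). Against partial exposure or a swap, its integrated stress response genes lay at -0.00677 on a scale from vehicle (0) to treated (1), and its deviations correlated at -0.0797 with those of treated replicate 2. A bias by GC content stays open as a candidate explanation, since its deviations followed GC content with a Spearman rho of -0.472 over the 97.0% of genes with a value, against at most 0.171 in size in the other vehicle libraries (gene length 0.170 against 0.183). The design names no biological difference for a single batch.

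The mtDNA rRNA share of reads rose while the mRNA share fell. Counting of mRNA reads in nuclear copies is argued against by the amount, since these copies held at most 0.0321% of reads in a treated library while the mRNAs lost 1.30 points without vehicle replicate 2, and vehicle replicate 2 alone by the remaining libraries, whose lowest treated ratio of rRNA to mRNA (1.11) was 5.34 times the highest vehicle ratio (0.207). Among 12 heavy-strand mRNAs the fold change did not fall with distance from the promoter (rho 0.112, permutation p = 0.733). This argues against the hypothesis of a gradual loss of heavy-strand transcription across these mRNAs. The test left out the rRNA genes, which rose (MT-RNR1 by 2.92 and MT-RNR2 by 1.53), so it cannot judge a stop between them and the mRNAs. Weaker poly(A) selection in treated libraries cannot be told apart from a change in the cells, because 15 nuclear RNAs without a poly(A) tail had a median of -0.0650 with an interval of -0.465 to 1.00. Of these 3 rose, RN7SK, singled out after its value was seen, by 1.10, and 1 fell, and 23 of 38 replication-dependent histone genes rose, so both that and an effect of the inhibitors on mtDNA transcripts stay open.

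Among changed lncRNA genes 66.6% fell. Abundance and scaling are argued against, since coding genes matched on CPM gave at most 49.8% falls (median 45.5%, 1000 draws) and the lowest share over 7 scaling settings was 65.7% (highest 71.9%). In changed lncRNAs with a coding gene starting within 2 kb on the other strand 88.4% fell (551 of 623), against 54.0% (583 of 1079) without one, a difference of 34.4 points (permutation p = 0.0001, the smallest possible), so a hypothesis is that lncRNAs beside coding promoters fall most. GC-matched coding genes gave at most 57.6% (median 49.8%), and where the gene bodies did not overlap 91.7% of 302 fell (85.4% of 321 with overlap), which argues against GC content and overlapping reads. Whether these lncRNAs follow their neighbours stays open, with the same sign in 51.0% of 367 pairs where both changed (45.9% when shuffled, permutation p = 0.0036), while 86.4% of the lncRNAs and 44.4% of the partners fell. The permutations in this paragraph ran over genes or pairs of genes, which are not independent replicates. Their p-values do not measure the spread between differentiations.

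Other single libraries stood apart in named genes. In vehicle replicate 3 these were HMOX1 (ratio 0.930), GABARAPL1 (0.929), KCNS2 (0.892), JDP2 (0.863), XPC (0.861), YARS1 (0.856) and SLC2A3 (0.836). In treated replicate 5 they were lnc-TTC34 (0.868), DLG4 (0.835) and KRT40 (0.830). Vehicle replicate 4 stood apart in lnc-CRHR2 (0.907) and SOX2 (0.836), vehicle replicate 5 in GADD45A (0.895) and FGF21 (1, as the only vehicle library with a read), and treated replicate 2 in lnc-MT-ND6 (0.885).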

How the results depend on the processing

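The FPKM settings named here were chosen after seeing the data. Gene counts stayed within 1.5 times the reported ones under other scaling factors, filters, tests and offsets, except that lncRNA genes came to 773 with a CPM of at least 1 in 4 libraries, where fewer genes were tested, and that an absolute log2 fold change of at least 1 left 3419 genes, 1965 coding, 905 lncRNA and 16 unannotated lncRNA genes, and 32 of the 378 changed lncRNAs known to the authors' catalogue. At a mean FPKM of at least 1, with fewer tested, unannotated lncRNAs came to 50 and known ones to 246. Settings for counts do not apply to them. Genes with changed transcript usage came to 452 among transcripts with at least 10% of their gene's reads and to 3039 by the gene-level F-test, and the cause was not tested. Of the 16 lists 2 passed with an estimated correlation, 15 passed by fry, and 15 of all 38 lists stood on the same side of the threshold in all settings run for them. Another 8 lists passed by fry, in the camera direction, that camera did not call. Fry turned the astrocyte markers upward (adjusted p = 8.25e-04, and up to 0.998 in other settings) against a camera direction of down with no call, and the cause was not tested. The mtDNA mRNA difference was -0.944 points with the mtDNA rRNAs added (exact p = 0.943), since the rRNA share moved the other way. Leaving out 1 library at a time gave 10214 to 12702 genes, 7612 to 9627 coding, 1589 to 1832 lncRNA and 66 to 90 unannotated lncRNA genes, 578 to 1483 genes with changed usage, 14 to 16 lists, and mtDNA differences of -1.30 to -4.04 points. Without treated replicate 2, 3, 4 or 5 the usage count was 580, 583, 578 or 636. The groups have the same differentiation numbers, which may or may not mark shared batches. Same-numbered deviations correlated at -0.080, 0.032, 0.025 and -0.001, and no library correlated best with its own number. With the number as a replicate block, counts were 10764 genes, 8104 coding, 1616 lncRNA and 71 unannotated lncRNA genes, 728 genes with changed usage and 15 lists, autophagy being lost (adjusted p = 0.058), with 6486 genes past in both tests beside the authors' table (6827 with DESeq2). The paired mtDNA difference was -3.19 points with an exact sign-flip p = 0.125, the smallest of 16. Of 162 named genes past the threshold 147 stayed past it with the same sign in each of the 18 settings that could be run for them, as some had no value without mtDNA genes, with DESeq2 or with a CPM of at least 1. Those that did not were H2AC18, PDK1, HSPD1, PPARGC1A, PDCD6-AHRR, MTFR2, TFB1M, ATP5MF, ATP6V1H, NDUFB9, MALAT1, H4C16, ATP5MC2, COX5A and PLA2G6, and PINK1, not past the threshold in the reported test, passed in some. Of the named unannotated lncRNAs only lnc-MT-ND6 lost its call in any setting.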

Other observations

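The test of nonsense-mediated decay transcripts was chosen before its result was seen, and those of other splits of the libraries after. Genes of the p53 and cell death lists moved both ways. Of 18 p53 targets 10 rose and 4 fell (median 0.22, camera adjusted p = 0.093), with the cell cycle inhibitor CDKN1A up from 17.7 ± 3.43 to 182 ± 28.7 CPM (3.36) and GADD45A (1.34) also higher, and with XPC (-0.58) and TP53INP1 (-0.57) lower. The median of this list in vehicle replicate 2 was -0.30 log2 units from the other vehicle libraries. Of 12 tested BCL2 family genes 6 rose and 3 fell (median 0.42, adjusted p = 0.21). The pro-apoptotic genes PMAIP1, from 5.72 ± 0.556 to 54.3 ± 1.91 CPM (3.25), and HRK (1.84) rose, while BMF (-0.67) and the anti-apoptotic BCL2L1 (-0.65) fell. Of 17 immediate early genes 8 rose and 6 fell (median 0.29, adjusted p = 0.52). NR4A1 (2.84) and JUN (1.73) rose, EGR1 (-1.52) fell, and EGR4 (-4.10) fell from 0.463 ± 0.160 to 0.0256 ± 0.0134 CPM. FOS stood at 0.29 ± 0.277 (adjusted p = 0.40). Of 9 tested interferon response genes 2 rose, RIGI (1.82) and ISG15 (1.07), and 2 fell, among them STAT2 (-0.62), with a median of -0.08, a mean of 0.13 and an adjusted p of 0.86.

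Markers of other cell types showed no common direction. Of 12 progenitor markers 4 rose and 5 fell (4 and 6 adjusted over the list alone, median -0.24, camera adjusted p = 0.63), with SOX2 (1.43) and PAX6 (0.76) higher and the Notch targets HES5 (-2.70) and HES1 (-1.25) lower. SOX2 rose from a low level, 0.447 CPM in vehicle replicate 4 and 0.253 to 0.285 CPM in the other vehicle libraries. Of 5 tested astrocyte markers the glutamate transporter SLC1A3 rose from 3.0 ± 0.51 to 28.8 ± 0.762 CPM (3.26), while SLC1A2 (-0.75) and GJA1 (-0.40) fell (median -0.17, mean 0.44, adjusted p = 0.88). Of 5 tested oligodendrocyte lineage markers 3 fell, among them OLIG1 (-0.77) and OLIG2 (-0.52), and none rose (adjusted p = 0.54). Of 5 tested markers of other neuron types SLC32A1 (1.54) and CHAT (0.62) rose and SLC18A3 fell (-1.25, adjusted p of the list 0.57). None of 9 microglia markers passed the filter on low counts. Of 38 tested replication-dependent histone genes 23 rose and 2 fell (median 0.60, adjusted p = 1.3e-04, and adjusted p = 0.23 with an estimated correlation), with H2BC15 (1.42) and H2AC6 (1.31) higher and H4C16 (-0.59) and H2AC18 (-0.48) lower. The call of H4C16 was lost under a length offset (-0.27), and that of H2AC18 without treated replicate 2 or 4 or vehicle replicate 4 (-0.39 to -0.41). Genes of the assembly without an Ensembl identifier took 2.33 ± 0.479% of reads in treated and 1.15 ± 0.430% in vehicle cells (exact permutation p = 0.0286), most of them in MSTRG.18495 (21178 ± 4244 against 9122 ± 3801 CPM), which was singled out after its values were seen. So was MSTRG.121, which fell from 110 ± 12.4 to 5.50 ± 0.969 CPM (-4.32, edgeR adjusted p = 1.4e-08).

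A hypothesis was that transcripts annotated as targets of nonsense-mediated decay take a larger share of coding gene reads under the inhibitors. Their share was 2.47 ± 0.00878% in treated and 2.27 ± 0.312% in vehicle cells, a difference of 0.203 points (exact permutation p = 0.143), which leaves the hypothesis open. Without vehicle replicate 2 (2.74%) the vehicle share was 2.11 ± 0.0324% and the difference 0.359 points (exact p = 0.0286), with all treated libraries higher. Retained intron transcripts held 4.53 ± 0.259% and 4.10 ± 0.352% (exact p = 0.0857).

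The 8 libraries can be split into groups of 4 in 35 ways. Only 1 split, the real one, gave as many genes (11461, highest other 1), coding genes (8668, highest other 1), lncRNA genes (1702, highest other 0), unannotated lncRNA genes (78, highest other 1) and genes with changed usage (1005, highest other 178). That is 1 of 35, the smallest share these splits allow, so chance is unlikely rather than excluded. These counts come from the same libraries. The other splits mix the groups, which adds the treatment difference to the spread and lowers their counts. For gene lists 6 splits gave 16 or more, the highest other 18. Apart from the real one, these splits kept most libraries of 1 treatment together, so they still held part of the treatment difference. Splits with equal numbers of treated and vehicle libraries on each side gave 0 to 12 lists. The splits therefore cannot decide whether chance gives as many lists passing camera with a preset correlation, and lists can pass it with no treatment contrast.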
